A study of Homo sapiens with 6 samples.

How the data were processed

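RNA from cultured human skin fibroblasts was hybridised to 6 Illumina bead arrays, a platform on which each gene is read by 1 or more short probes attached to beads. The labels put 3 arrays in a group treated with lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) for 6 h and 3 arrays in a control group. Per the labels, total RNA was extracted with a column kit and labelled with biotin. The deposited values are on a log2-like scale, and the submitters' processing notes name BeadStudio and lumi without versions. Whether the scale is a plain log2 or a variance-stabilising transform with a similar range is not given in the sources used here, so differences are given in log2 units of the deposited values and not as folds. The table held 47323 probes, with values from 7.16 to 13.98 and a median of 7.35 in each of the 6 arrays. The sorted values of the 6 arrays differed by at most 0.000634, which is what quantile normalization leaves. A total shift in RNA between groups was therefore not measurable. The lower quartile of all values was 7.29, so a difference between values near the bottom of the range is compressed. The table carries no detection p, and no probe could be called present or absent. The number of arrays limits the precision. The sources name no slide, scan day or culture, so batches were not testable, and p-values measure only the spread between these samples, which may be technical.

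Probes were named through the platform annotation table. Of the 47323 probes, 30113 had 1 gene symbol, 8 had several, and 17202 were not listed there and stay unnamed. Symbols were updated through gene numbers against the GRCh38.p14 gene table, where 30074 probes matched and 47 kept the annotation's symbol. The probe with the highest mean over the 6 arrays stood for its gene, which gave 19951 genes. XIST and genes of chromosome Y were left out of every gene-level result. No coordinates are given, because the sources name no genome build for the probes. Genes of the fixed lists without a named probe here were not analysed here.

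Each probe was tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, without trend or robust options), LPS-labelled minus control-labelled, with no filter on dim probes. P-values were adjusted over all 47323 probes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The tests were two-sided. Errors are SD over 3 arrays or the moderated standard error (SE) of the difference. Before the data were examined, 21 gene lists and 6 lists of cell type markers were fixed, together with the tests between the groups and of these lists, their alternatives except 1, and the rule for the genes to be named. The tests of the closing section were set later, most of them after the result they measure was seen. That rule takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap. It also takes up to 4 members of each list with the largest absolute difference, called or not, and 11 genes chosen in advance: TLR4, CD14, LY96, MYD88, IL6, CXCL8, CCL2, COL1A1, COL1A2, ACTA2 and BAMBI. Any other gene named below was chosen after its values were seen. Lists were tested against all other genes with camera (preset inter-gene correlation 0.01), adjusted over the 21 lists, and the marker lists were adjusted apart. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. For each list, a further count of calls was made with p-values adjusted over the list alone.

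The test was tried on simulated arrays built from the real probe means and the SD of the control-labelled arrays, with 47323 probes of which 200 were shifted. With equal spread in both groups, 85.5% of shifts of 1 and 98% of shifts of 2 log2 units were called, with 13 and 11 false calls. Where the shift itself varied between the LPS-labelled arrays with an SD of 0.5 times its size, only 3.5% of shifts of 1 and 2% of shifts of 2 were called, although 99.5% and 100% had the right sign. In this simulation, shifts that differed strongly between arrays were thus mostly missed. The adjusted p depends on how many probes change, and 5683 probes were called in the data. The shares recovered here therefore do not carry over to the data.

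Alternatives planned in advance were a second quantile normalization, centring on the median, a filter on dim probes, leaving out each array, the sample number as a replicate block, other variance models, thresholds and set tests, and the mean of all probes of a gene. An alternative for linear values did not apply. Array weights were added after the data were seen. The share of control-like RNA in an array was estimated after the data were seen, on the linear scale, taking the deposited values as plain log2. It used probes that differed by more than 1.5 log2 units between the control mean and LPS sample 3, and simulated shares of 0.2 and 0.6 were recovered as medians of 0.192 to 0.196 and 0.605 to 0.608. Figures were drawn with matplotlib version 3.10.9.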

Results

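The data describe how LPS changes gene expression in confluent human skin fibroblasts, the connective tissue cells of the dermis, kept in medium without serum. There were 3 arrays in each group. The labels are not fully clear about the control group: the design text sets LPS against no LPS for 6 h, while the titles of the 3 control arrays describe cells transfected with an empty vector, and the titles of the LPS arrays mention no transfection. Several genes that LPS is known to induce in fibroblasts, such as IL6, CXCL8 and CXCL10, averaged higher in the control arrays without passing the test (adjusted p from 0.142 to 0.158). Of other such genes, CSF3 (-0.47), IL1B (-0.60), CCL7 (-0.70) and CCL20 (-0.17) were called lower in the LPS-labelled arrays (adjusted p from 0.00513 to 0.0342), while VCAM1 rose by 1.76 on 1 of its 3 probes (adjusted p = 0.00251). The groups are therefore called LPS-labelled and control-labelled throughout, and each direction below is that of the labels as deposited.

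Matrix and contractile genes more often rose than fell in the LPS-labelled arrays (17 and 3 of 37, 10 and 1 of 17), and interferon, cytokine and glycolysis genes more often fell than rose (4 and 0 of 39, 11 and 1 of 32, 12 and 1 of 23). The 4 of 39 interferon genes called lower lie near the share over all genes, 1858 of 19951. VEGFA counts in both the cytokine and the glycolysis list. Camera called these lists, but none of the 21 lists with an estimated correlation (adjusted p of 0.312 or more), and the counts varied with the array left out. Of 19951 genes, limma called 3617, of which 1759 were higher and 1858 lower in the LPS-labelled arrays. With LPS sample 1 left out these counts were 964, 581 and 383. A difference of at least 1 log2 unit was reached by 318 of the higher and 139 of the lower genes. The largest rise was in OLFML2A, an extracellular olfactomedin-domain protein, from 7.59 ± 0.07 to 11.01 ± 0.59 (SD, n = 3 arrays per group), a difference of 3.42 ± 0.29 (SE) with an adjusted p of 0.00487. FBN2, which encodes the microfibril protein fibrillin-2, rose by 3.08 (adjusted p = 0.000844), and MFAP5, another microfibril protein, rose by 3.06. The signalling protein gene WNT2 rose by 3.00 and the retinaldehyde dehydrogenase gene ALDH1A1 by 2.82. PSAT1, of serine synthesis, rose by 2.89, with a second probe at 0.04. CLEC3B rose by 2.81, ACO1 by 2.69, POSTN by 2.64, VGLL3 by 2.61, and COL1A1 and CXCL12 by 2.45 each. These 12 rises stayed called when any 1 of the 6 arrays was left out.

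The largest called falls were smaller and varied more between the LPS-labelled arrays. PARP12, an interferon-induced ADP-ribosyltransferase, fell by 1.89 (SE 0.43, adjusted p = 0.0475), and FOSL1, a subunit of the AP-1 transcription factor, fell by 1.86 (adjusted p = 0.0361). MT1G, a metallothionein, fell by 1.69 (adjusted p = 0.00832) and VEGFC, a lymphatic growth factor, fell by 1.63 (adjusted p = 0.0462). The other falls were those of PNP (-1.69), TAP2 (-1.68), HES4 (-1.67), DUSP5 (-1.62), MEDAG (-1.60), BATF2 (-1.60), ITPRIP (-1.59) and GMPR (-1.58). Of these 12 falls, only MT1G stayed called without LPS sample 1 (adjusted p = 0.0464) or without any 1 control array, while all 12 stayed called without LPS sample 2 or 3. The calls lost without LPS sample 1 did not come with smaller differences. All of these falls but that of MT1G (-1.67) were larger there, with FOSL1 at -2.01 and HES4 at -1.79. A further 148 genes were at least 1 log2 unit lower and not called. In 147 of them all 3 LPS-labelled arrays lay under all 3 control-labelled arrays. Some of these, such as OASL (-2.78) and CCL5 (-2.52), differed by more than any of the 12 called falls. The smaller size of the called falls thus depends on the test. Among genes at least 1 log2 unit lower, the median SD was 0.60 in the LPS-labelled and 0.12 in the control-labelled arrays. Over all genes, groups did not overlap in 38.8%, where chance gives 10% on average. Genes vary together over these arrays, so the share in a single split can lie far from that average by chance.

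**Figure D1:**
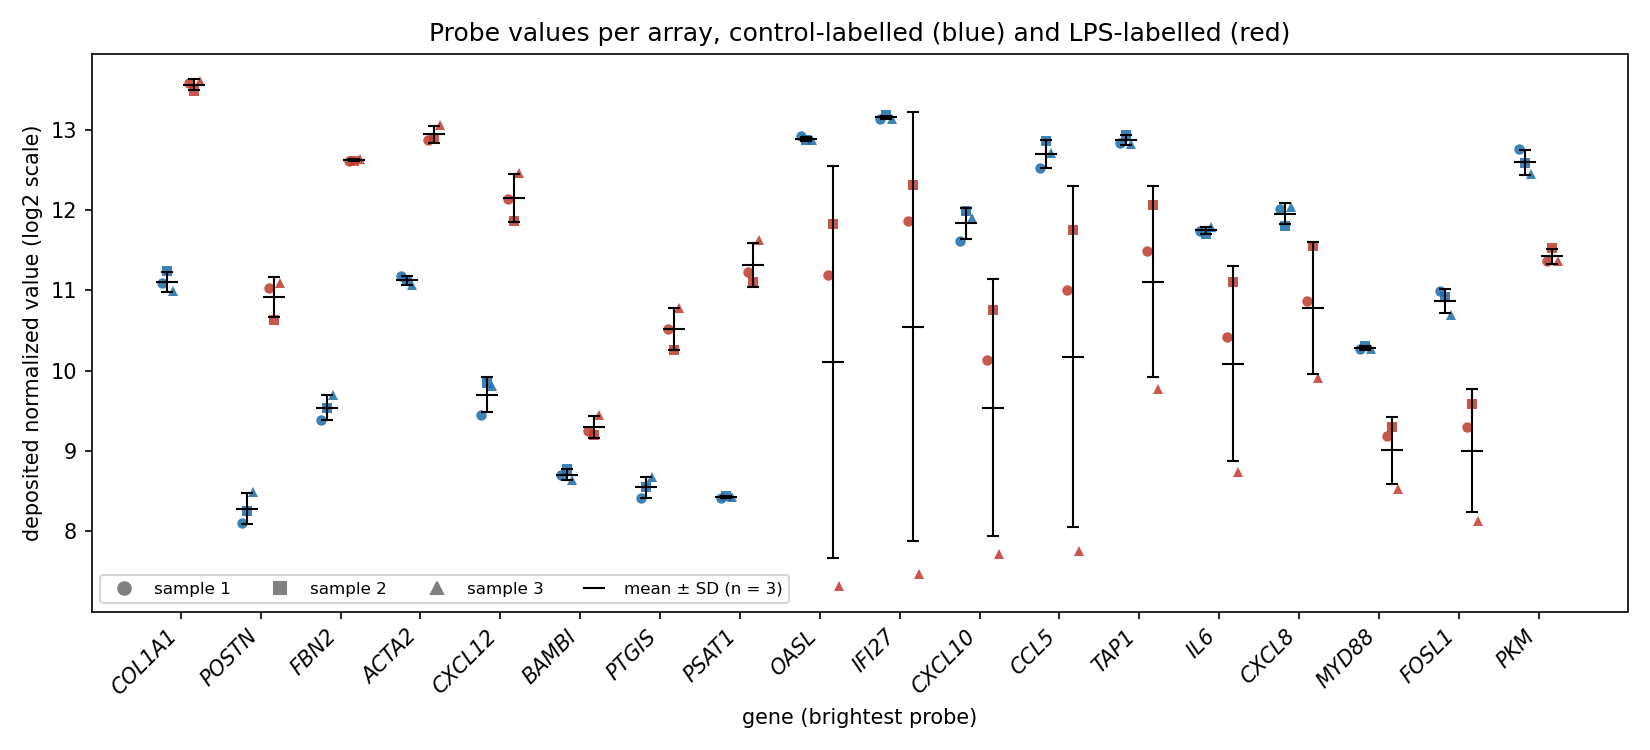
Deposited normalized values (log2 scale, vertical axis) of 18 genes in each of the 6 arrays, control-labelled in blue and LPS-labelled in red, with the mean and SD of 3 arrays in black. COL1A1, FBN2 and ACTA2 lie close together within each group and apart between groups, while OASL ranges from 7.32 to 11.82 over the LPS-labelled arrays and stays between 12.87 and 12.91 in the control-labelled arrays.

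Extracellular matrix genes more often rose than fell in the LPS-labelled arrays. Of 37 measured members, 17 rose, 3 fell and 17 did not pass the test (21 higher and 4 lower when adjusted over the list alone), with a median difference of 0.35. COL1A1, the main chain of type I collagen, rose from 11.10 ± 0.12 to 13.56 ± 0.07. POSTN (periostin) rose by 2.64, the proteoglycan gene VCAN by 1.80 and COL12A1 by 1.79, with a second COL12A1 probe at 0.01. COL1A2 rose by only 0.23 from a mean of 13.64, near the top of the scale. The 3 members that fell were the hyaluronan synthase HAS2 (-1.28), TNC (-0.79) and P4HA2 (-0.59). Camera placed the list above other genes with an adjusted p of 1.27e-07. With an estimated correlation, which ended the call of every list, the adjusted p was 0.312. The number that rose was 11 without LPS sample 1 and 14 to 20 without another array.

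Contractile genes of the myofibroblast, a fibroblast that carries smooth muscle actin, shifted the same way. Of 17 members, 10 rose, 1 fell and 6 did not pass (14 higher and 2 lower when adjusted over the list alone). ACTA2, which encodes smooth muscle actin, rose from 11.12 ± 0.06 to 12.94 ± 0.11 (difference 1.82, adjusted p = 0.00111). The calponin CNN2 rose by 1.80, PALLD by 1.43 and the tropomyosin TPM1 by 1.17, and the member that fell was ACTG2 (-0.39). The camera adjusted p was 6.23e-07, and the adjusted p 0.312 with an estimated correlation. The number that rose was lowest, at 6, without LPS sample 1 or control sample 2, and ACTG2 was not called in any of the 6 fits that left out an array.

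In the TGF-beta list, 8 of 28 members rose, 4 fell and 16 did not pass (11 and 7 when adjusted over the list alone), and the list passed with fry as higher (adjusted p = 0.0212) but not with camera (adjusted p = 0.311). LTBP2, a latent TGF-beta binding protein, rose by 1.88, PMEPA1 by 1.28 and the inhibitory SMAD6 by 0.91, and the co-receptor ENG fell by 1.36. BAMBI, a decoy receptor that LPS lowers in some mesenchymal cells, rose from 8.71 ± 0.07 to 9.30 ± 0.13 (difference 0.59, adjusted p = 0.0111). PMEPA1 was not called without LPS sample 1 (adjusted p = 0.0518), and 3 members of the list rose and 1 fell there.

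Interferon-stimulated genes had their higher values in the control-labelled arrays. All 39 measured members averaged lower in the LPS-labelled arrays, with a median difference of -1.85, and in 38 of them the groups did not overlap. Only 4 members fell by the test over all probes, IRF9 (-1.10), IFIT5 (-0.67), IFITM3 (-0.41) and IFNB1 (-0.35), and 17 when adjusted over the list alone. The list's shift was called by camera (adjusted p = 2.10e-08) but not by fry (adjusted p = 0.0704), and the adjusted p was 0.394 with an estimated correlation. The 4 members with the largest differences did not pass. OASL, which binds the sensor of viral RNA, averaged 12.89 ± 0.02 in the control-labelled and 10.11 ± 2.44 in the LPS-labelled arrays (adjusted p = 0.238). IFI27 averaged 13.15 and 10.55 (adjusted p = 0.319), OAS1 12.08 and 9.50 (adjusted p = 0.151) and RSAD2 13.36 and 10.86 (adjusted p = 0.397).

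LPS sample 3 lay apart from the other LPS-labelled arrays in this list. The median difference of the list from the control mean was -1.25 in LPS sample 1, -0.80 in LPS sample 2 and -3.54 in LPS sample 3. OASL read 11.19, 11.82 and 7.32 in LPS samples 1, 2 and 3, the last near the bottom of the scale. Without LPS sample 3, 29 of the 39 members fell, with OASL at an adjusted p of 0.0193. Without LPS sample 2, 18 fell. In the fits without LPS sample 1 or any 1 of the control-labelled arrays, limma called 0, where 15 to 23 had an unadjusted p under 0.05.

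Antigen presentation genes followed the same order. Of 15 members, 4 fell and 11 did not pass (11 lower when adjusted over the list alone). TAP2, a subunit of the peptide transporter, fell by 1.68, and TAPBP (-0.69), NLRC5 (-0.63) and CD74 (-0.22) were the others that fell. TAP1 averaged 12.87 ± 0.06 and 11.11 ± 1.19 (adjusted p = 0.13), HLA-C 11.29 and 9.53 (adjusted p = 0.0533) and HLA-F 13.16 and 11.81 (adjusted p = 0.0875). A second HLA-C probe differed by -0.10. By camera the adjusted p was 3.37e-05, and the adjusted p was 0.333 with an estimated correlation. The number that fell was 1 without LPS sample 1 or control sample 2, 2 and 3 without the other control arrays, and 9 and 8 without LPS samples 2 and 3.

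In the list of TLR4, the LPS receptor, and its signalling chain, 2 of 25 members rose, 5 fell and 18 did not pass (4 and 15 when adjusted over the list alone). MYD88, the adaptor of the receptor, fell from 10.28 ± 0.02 to 9.01 ± 0.42 (difference -1.28, adjusted p = 0.0191), and the kinase IKBKB fell by 0.67, with a second probe at -0.02. The co-receptor CD14 fell by 0.55 (adjusted p = 0.0339), as did TICAM1 (-0.53) and TRAF6 (-0.34), and IRAK3 (0.55) and MAP3K7 (0.36) rose. TLR4 itself read 7.40 ± 0.03 and 7.37 ± 0.02, at the bottom of the scale, and LY96 11.13 ± 0.34 and 10.56 ± 0.16, neither passing the test. IRAK2 averaged 10.57 and 8.93, and TLR3 8.38 and 7.64, also without passing. For the list, camera returned an adjusted p of 0.00437, and an adjusted p of 0.312 with an estimated correlation. MYD88 and CD14 were each called in 2 of the 6 fits that left out 1 array, MYD88 not without LPS sample 1 (adjusted p = 0.0643) and CD14 not without LPS sample 3 (adjusted p = 0.0736). Without LPS sample 1, control sample 1 or control sample 2, 1 member fell and limma called 0 higher (2 or 3 at an unadjusted p under 0.05).

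Factors and feedback inhibitors of NF-kB, the transcription factor downstream of the receptor, more often fell than rose in the LPS-labelled arrays. Of 24 members, 1 rose, 7 fell and 16 did not pass (1 and 10 when adjusted over the list alone). IER3 fell by 1.36 (adjusted p = 0.0397) and NFKBIZ by 0.99 (adjusted p = 0.0474), and the member that rose was TNFAIP2 (0.19), where limma called 0 members higher without LPS sample 1, control sample 2 or control sample 3 (1 to 3 at an unadjusted p under 0.05). SOD2, the mitochondrial superoxide dismutase, averaged 13.70 and 12.15 (adjusted p = 0.2), and TNFAIP3 9.55 and 8.63 (adjusted p = 0.0675). The list passed with camera (adjusted p = 0.00933), with an adjusted p of 0.312 with an estimated correlation. IER3 was not called without LPS sample 1 (adjusted p = 0.135), and 3 members fell without LPS sample 1, control sample 1 or control sample 2.

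Cytokines and growth factors were lower as a list. Of 32 members, 1 rose, 11 fell and 20 did not pass (2 and 16 when adjusted over the list alone), with a median difference of -0.31. IL24 fell from 9.11 ± 0.02 to 7.83 ± 0.50 (difference -1.28, adjusted p = 0.03), and the member that rose was BDNF (0.33). IL6 averaged 11.75 ± 0.05 and 10.08 ± 1.22 (adjusted p = 0.158), TNFSF10 10.90 and 9.11 (adjusted p = 0.21) and IL33 9.41 and 8.06 (adjusted p = 0.0541). The camera adjusted p was 0.000202, and the adjusted p 0.312 with an estimated correlation. IL24 was not called without LPS sample 1 (adjusted p = 0.0903). The number that fell was 2 to 4 without LPS sample 1 or any 1 control array.

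Chemokines went both ways. Of 23 members, 2 rose, 3 fell and 18 did not pass (2 and 6 when adjusted over the list alone). CXCL12, a chemokine that fibroblasts make at rest, rose from 9.70 ± 0.22 to 12.15 ± 0.30 (adjusted p = 0.0039), as did CXCL14 (1.19), while CXCL16 (-0.91), CCL7 (-0.70) and CCL20 (-0.17) fell. CCL5 averaged 12.69 ± 0.17 and 10.17 ± 2.12 (adjusted p = 0.219), CXCL10 11.83 and 9.54 (adjusted p = 0.142), CCL26 10.64 and 8.74 (adjusted p = 0.117), CXCL8 11.95 and 10.78 (adjusted p = 0.147) and CCL2 12.95 and 12.16 (adjusted p = 0.0502). The list did not pass with camera (adjusted p = 0.0588), but it did without LPS sample 3 (adjusted p = 0.0327) or LPS sample 2 (adjusted p = 0.0225), while the highest adjusted p with 1 array left out was 0.106 and that with an estimated correlation 0.344. Without LPS sample 3, CCL5 (adjusted p = 0.041), CXCL10 (adjusted p = 0.0264) and CCL26 (adjusted p = 0.0337) passed too, while limma called 0 members lower without LPS sample 1, control sample 2 or control sample 3, where 7 to 9 had an unadjusted p under 0.05.

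Immediate early genes and feedback inhibitors of MAP kinase fell as a list. Of 29 members, 2 rose, 12 fell and 15 did not pass (2 and 18 when adjusted over the list alone), and camera gave an adjusted p of 6.59e-05, against an adjusted p of 0.312 with an estimated correlation. FOSL1 and DUSP5 are given above, ATF3 fell by 1.22 (adjusted p = 0.0376) on 1 of its 3 probes, which ranged from -1.22 to 0.02, and SPRY2 averaged 11.64 and 10.30 (adjusted p = 0.0533). With the mean of its probes ATF3 was not called (difference -0.39, adjusted p = 0.0522). The 2 members that rose were EGR1 (0.49) and EGR3 (0.24), but 1 member rose without LPS sample 3 and limma called 0 higher in the other 5 fits that left out an array (2 or 3 members higher at an unadjusted p under 0.05). The number that fell was 1 to 4 without LPS sample 1 or any 1 control array, and ATF3 was not called without LPS sample 1 (adjusted p = 0.118).

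Genes of glycolysis and the response to low oxygen were lower in the LPS-labelled arrays. Of 23 members, 1 rose, 12 fell and 10 did not pass (1 and 18 when adjusted over the list alone), with a median difference of -0.62. PKM, the last enzyme of glycolysis, fell from 12.59 ± 0.16 to 11.42 ± 0.09 (difference -1.17, adjusted p = 0.00405), and PFKFB3 and PFKP each fell by 1.12. The kinase HK2 averaged 10.54 and 8.83 (adjusted p = 0.0769), and the member that rose was EGLN3 (0.14, from 7.32), which limma did not call in any of the 6 fits that left out an array. By camera the adjusted p was 3.01e-07, and the adjusted p was 0.312 with an estimated correlation. Without any 1 control array 4 or 5 members fell. Without LPS sample 1, 3 members fell, PKM among them (adjusted p = 0.0295), and PFKFB3 was not called (adjusted p = 0.0842).

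Of the other lists called by camera, metallothionein and oxidative stress genes had 2 of 21 members that rose and 7 that fell (2 and 13 when adjusted over the list alone, camera adjusted p = 0.0036). Besides MT1G, the zinc transporter SLC39A14 fell by 0.92 and catalase (CAT) rose by 0.85, while MT2A averaged 13.77 and 12.56 (adjusted p = 0.316). In the list of TNF receptors and cell death genes, 0 of 27 rose and 7 fell (2 and 11 when adjusted over the list alone, camera adjusted p = 0.00846). TNFRSF21 fell by 1.21 and CASP1, the caspase that processes interleukin-1 beta, by 1.09, while PMAIP1 averaged 11.57 and 9.59 (adjusted p = 0.171) and TNFRSF11B 12.32 and 11.60 (adjusted p = 0.252). Of 28 cell cycle genes, 2 rose and 7 fell (2 and 13 when adjusted over the list alone, camera adjusted p = 0.000849). MCM7, of the replicative helicase, fell by 0.74 (adjusted p = 0.00111), with another probe at -0.04, CCND1 fell by 0.80 and AURKB by 0.71, while MCM4 averaged 9.36 and 8.62 (adjusted p = 0.128). With an estimated correlation the adjusted p of these lists was 0.312, 0.333 and 0.312 in the order given. Without LPS sample 1, these lists had 2, 1 and 1 members that fell, and SLC39A14, TNFRSF21, CASP1, CCND1 and AURKB were not called there (adjusted p from 0.0649 to 0.105). Without any 1 control array, 3 to 5, 2 to 4 and 3 or 4 members fell. The number of cell cycle genes that rose was 1 without any 1 LPS array, and limma called 0 higher without any 1 control array (2 or 3 at an unadjusted p under 0.05).

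**Figure D2:**
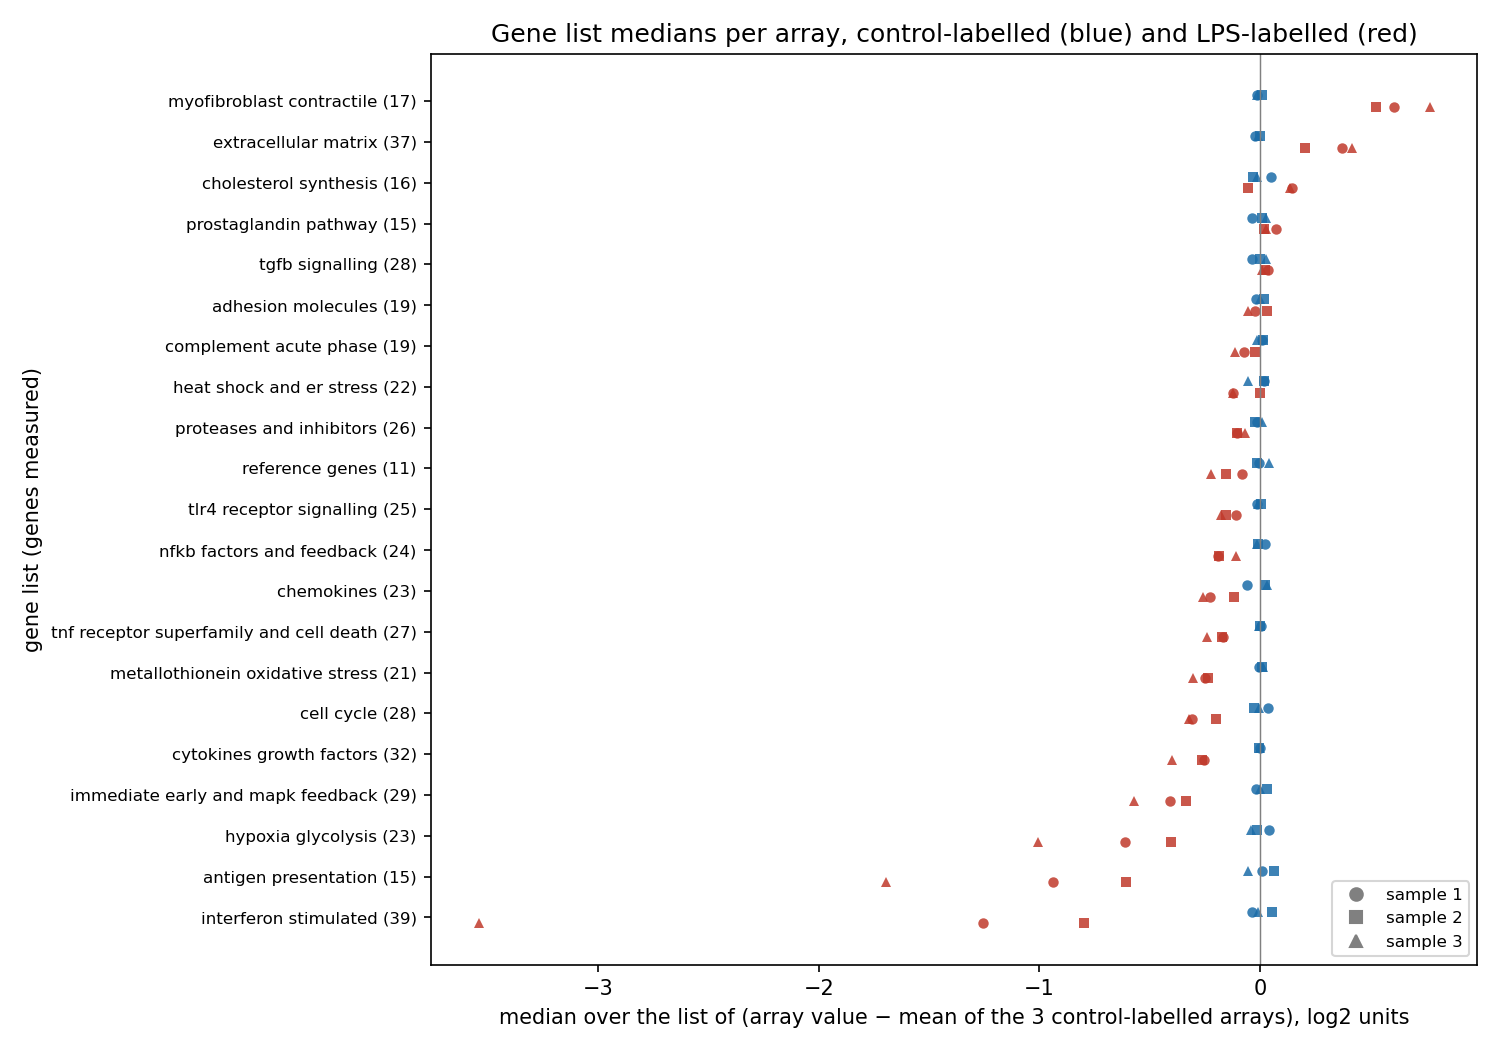
Median over each of the 21 fixed lists (vertical axis, with the number of genes measured) of each array's difference from the mean of the control-labelled arrays, in log2 units (horizontal axis), with 1 point per array and a marker for each sample number. The interferon list reaches -3.54 in LPS sample 3 and -0.80 in LPS sample 2, and the contractile and matrix lists lie above 0 in all 3 LPS-labelled arrays.

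The remaining lists did not pass with camera, but fry called the prostaglandin list higher (adjusted p = 0.00999) and the reference genes lower (adjusted p = 0.00301). Of 19 adhesion molecules, 4 rose and 6 fell (6 and 8 when adjusted over the list alone), with a median of 0.0022, a mean of -0.05 and an adjusted p of 0.985. Limma called 0 of them lower without LPS sample 1, control sample 1 or control sample 2 (6, 7 and 7 at an unadjusted p under 0.05). VCAM1, an adhesion receptor for leukocytes, rose by 1.76 on 1 of its 3 probes, which ranged from -0.02 to 1.76 (mean of probes 0.75), and the integrin ITGAV by 1.78. ITGA3 fell by 1.53, and ITGA2 averaged 11.28 and 9.36 (adjusted p = 0.149). In the prostaglandin pathway, 5 of 15 rose and 1 fell (5 and 3 when adjusted over the list alone). The member that fell was PTGES (-0.90), and limma called 0 lower without LPS sample 1, control sample 1 or control sample 3 (3 or 4 at an unadjusted p under 0.05). PTGIS (prostacyclin synthase) rose by 1.97, PTGDS by 1.73 and PTGFR by 1.17, while PTGS2, the inducible cyclooxygenase, averaged 11.20 and 9.53 (adjusted p = 0.197). PTGDS and PTGFR were not called without LPS sample 1 (adjusted p = 0.0743 and 0.0779), where 1 member rose, as without control sample 1 or 2. Of 26 proteases and inhibitors, 3 rose and 5 fell (5 and 9 when adjusted over the list alone). PLAT, the tissue plasminogen activator, fell by 1.25, while the urokinase PLAU averaged 12.58 and 10.70 (adjusted p = 0.053), its receptor PLAUR 10.51 and 8.95 (adjusted p = 0.0544) and the stromelysin MMP3 13.57 and 12.25 (adjusted p = 0.403). Without control sample 2 or LPS sample 1, limma called 0 proteases or inhibitors lower (9 and 10 at an unadjusted p under 0.05), and ITGA3 and PLAT were not called without LPS sample 1 (adjusted p = 0.125 and 0.0754).

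Of 19 complement and acute phase genes, 1 rose and 2 fell (2 and 6 when adjusted over the list alone). The riser was CFD at 1.38, CFB averaged 10.87 and 9.34 (adjusted p = 0.0558), CD59 8.78 and 9.50 (adjusted p = 0.0798) and CD55 9.50 and 8.89 (adjusted p = 0.0917). In the fit without LPS sample 1, limma called 0 members higher and 0 lower (2 and 5 at an unadjusted p under 0.05). Of 22 heat shock and endoplasmic reticulum stress genes, 5 rose and 4 fell (5 and 8 when adjusted over the list alone), with a median of -0.09 and a mean of 0.11. The risers included ASNS (asparagine synthetase, 2.28), TRIB3 (1.39) and DDIT4 (1.35), and the chaperone HSPH1 fell by 1.17. Limma called 0 of these genes lower without LPS sample 1 or control sample 2 (8 and 7 at an unadjusted p under 0.05), and 1 to 6 without another array, while 4 to 6 rose in each of these fits. Of 16 cholesterol synthesis genes, 1 rose and 1 fell (2 and 3 when adjusted over the list alone). HMGCS1 rose by 0.49 and IDI1 fell by 0.29, and limma called 0 members lower in 4 of the 6 fits that left out an array (3 or 4 at an unadjusted p under 0.05), while LSS differed by 0.36 (adjusted p = 0.471), NSDHL by -0.36 (adjusted p = 0.067) and INSIG1 by 0.31 (adjusted p = 0.141). Of 11 genes often used as references, 2 rose and 3 fell (3 and 6 when adjusted over the list alone), with RPL13A at 1.09, TFRC at 0.62 and PGK1 at -0.79, and YWHAZ averaged 12.08 and 11.55 (adjusted p = 0.051). The number of reference genes that fell was 5 without LPS sample 2, and 1 or 2 without another array. CFD, HSPH1, TFRC and PGK1 were not called without LPS sample 1 (adjusted p from 0.0551 to 0.122).

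Among cell type markers, the fibroblast list was higher in the LPS-labelled arrays, with 6 of 13 members that rose and 1, TWIST2 (-0.82), that fell (8 and 1 when adjusted over the list alone). Of the 6, COL1A1, COL1A2 and COL3A1 also belong to the matrix list and PDGFRA to the contractile list, so this is not a separate result. FAP rose by 0.83 and PDGFRA by 0.86, the latter not called without LPS sample 1 (adjusted p = 0.0748). The number of fibroblast markers that rose was 3 without LPS sample 1 or control sample 2. Adjusted over the 6 marker lists, the camera p was 0.00361, and an adjusted p of 0.204 with an estimated correlation. The other marker lists did not pass. Of 13 macrophage and leukocyte markers, limma called 0, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. The largest difference was that of CD68, a lysosomal protein that fibroblasts also express, at 12.74 and 11.25 (adjusted p = 0.143), and it passed without LPS sample 3 (adjusted p = 0.0145). FCER1G, AIF1 and ITGAM differed by at most 0.10 in size. Of 11 keratinocyte markers KRT10 rose by 1.25, and DSP (-0.25), SFN (-0.08) and CDH1 (0.03) did not pass. The keratinocyte median was -0.01 and the mean 0.08. Of 10 endothelial markers PECAM1 fell by 0.38 and TEK by 0.29, both from under 8, and ROBO4 (-0.03) and CLDN5 (0.03) did not pass. Of 7 melanocyte markers KIT rose by 0.78 and MITF by 0.63, and SOX10 (0.11) and PMEL (0.02) did not pass. Of 8 smooth muscle and pericyte markers CSPG4 fell by 0.66, KCNJ8 by 0.30 and ABCC9 by 0.27, and CNN1 (0.48) and MYH11 (0.41) did not pass. TWIST2, KRT10, PECAM1, TEK, MITF, CSPG4 and KCNJ8 were not called without LPS sample 1 (adjusted p from 0.0649 to 0.138), nor was ABCC9. Limma called 0 smooth muscle markers lower without control sample 2 (3 at an unadjusted p under 0.05), 0 keratinocyte markers higher without any 1 control array (1 in each), 0 endothelial markers lower without control sample 2 or 3 (2 in each) and 0 fibroblast markers lower without control sample 1 or 2 (1 in each). Of the melanocyte markers, 1 rose without any 1 control array.

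Some named genes have probes that disagree. A further probe of PFKP, NFKBIZ, ITGA3, IL24, CASP1, MITF, PMEPA1, TPM1, CD14, SOD2, IL33 and YWHAZ differed by -0.25 to 0.28, and the lowest of 3 CXCL12 probes rose by 1.00. With the mean of all probes of a gene, PGK1 (adjusted p = 0.0577) and PDGFRA (adjusted p = 0.0679) were not called, while IL33, HLA-C, PLAUR, YWHAZ, PLAU and CCL2 were (adjusted p from 0.0378 to 0.0498), the last 2 with a single probe each.

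The control-labelled arrays were closer to each other than the LPS-labelled arrays were. Pearson correlations across all probes ran from 0.994 to 0.996 among the control-labelled arrays and from 0.979 to 0.994 among the LPS-labelled arrays, where probes are not independent replicates. The mean correlation with the control-labelled arrays was 0.967 for LPS sample 1, 0.978 for LPS sample 2 and 0.938 for LPS sample 3. The first principal component held 83.3% of the variance. It placed the control-labelled arrays between -32.24 and -30.95, and LPS samples 1, 2 and 3 at 28.46, 12.99 and 53.91.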

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

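Repeating the quantile normalization or centring each array on its median left 3617 genes called, but the arrays already share 1 distribution, so these settings moved nothing and say nothing about stability. The dim-probe filter, the mean of all probes and array weights (added after seeing the data) kept the counts of genes and lists within 1.5 times, as did eBayes with trend and robust options for genes, where lists were not tested. Leaving out 1 array gave 964 to 4471 genes called, 581 to 2280 higher and 383 to 2191 lower. The lowest counts came without LPS sample 1 (964), control sample 2 (1232), control sample 1 (1359) and control sample 3 (1821). In these fits 942, 1180, 1293 and 1648 of the called genes were among the 3617. Fewer arrays lower the power of each such fit. However, the count rose to 4471 without LPS sample 2 and was 2989 without LPS sample 3. The number of arrays alone therefore does not account for this range. On the first principal component LPS sample 1 (28.46) lay between LPS samples 2 (12.99) and 3 (53.91). The fit without LPS sample 1 thus kept the LPS-labelled arrays that lay furthest apart, while leaving out LPS sample 2 or 3 removed an outer array. No other cause of this range was tested. A call lost without LPS sample 1 need not mean a smaller difference. MYD88 differed by -1.36 in that fit, against -1.28 with all arrays. Some other genes that lost the call differed by less there, such as IER3 (-1.33 against -1.36) and KCNJ8 (-0.25 against -0.30). An added limit of 1 log2 unit left 457 genes (318 higher, 139 lower), and an adjusted p under 0.01 left 738 (484 higher, 254 lower). A linear model without eBayes called 224 (160 higher, 64 lower).

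With the sample number as a replicate block, 2250 genes were called, 1035 of them lower. Deviations of same-numbered arrays from their group means correlated at 0.02, 0.17 and -0.14. None of the 3 LPS-labelled arrays correlated best with its own number. The LPS-labelled arrays lay much further apart than the control-labelled arrays, so these correlations cannot tell whether same-numbered arrays share a culture or batch. Camera called 12 of the 21 lists, 2 higher and 10 lower, and 12 or 13 when 1 array was left out. With an estimated correlation it called 0 lists, 0 higher and 0 lower, where 2 had an unadjusted p under 0.05. Fry called 14, of which 4 were higher. Counting each named gene once per setting, 1636 pairs of gene and setting stayed on the same side of the threshold, 256 lost and 103 gained the call. The 1636 include the second quantile normalization and the centring, which could move nothing, and genes that stayed uncalled. INSIG1, not called, turned to -0.047 with the mean of its probes. Values near the bottom of the scale limit what can be read, since 7.35 was the median and the lower quartile lay at 7.29.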

Other observations

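Of the tests below, those of the 4 gene families, of the equal share from both probe sets, of exchanged labels, of transfection and of leukocytes were chosen after the result was seen. Genes for the synthesis and uptake of serine, asparagine, arginine and proline were higher in the LPS-labelled arrays: 12 of 13 measured members rose. In the fits without LPS sample 1 or any 1 control array, 8 rose. The 12 included PSAT1 (2.89), ASNS (2.28), PHGDH, the first enzyme of serine synthesis, from 10.61 ± 0.18 to 12.76 ± 0.14 (SD, n = 3 arrays), and ASS1 (1.98). The amino acid transporter subunit SLC3A2 fell by 0.75, and limma called 0 members lower without control sample 1 or 2 (1 in each at an unadjusted p under 0.05). Genes of microfibrils and the basement membrane shifted too, with 9 of 16 that rose and 0 that fell, among them FBN2 (3.08), MFAP5 (3.06), the laminin LAMA2 (2.19) and LTBP4 (2.04). Camera gave adjusted p-values of 1.47e-09 and 4.12e-08, and an adjusted p of 0.0805 for both with an estimated correlation. LTBP4 was not called without LPS sample 1 (adjusted p = 0.0883). Both families were picked on these arrays, so their counts and p-values are not independent evidence of the direction.

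Of 73 measured ribosomal protein genes, 43 rose and 2, RPS27L (-0.39) and RPL29 (-0.35), fell, with RPS23 at 2.12, RPL22 at 1.59, RPL13 at 1.47 and RPL4 at 1.40. A second RPL13 probe read -0.19. These genes have many processed pseudogenes, which a short probe can also bind, so single members are uncertain. Limma called 0 members lower in 5 of the 6 fits that left out an array (2 or 3 at an unadjusted p under 0.05). The number that rose was 20 without LPS sample 1 and 24 to 30 without any 1 control array. Of 64 histone genes of the replication clusters, 12 fell and 0 rose, H2BC21 (-1.26) among them. Near-identical H2A genes averaged higher in the control-labelled arrays without passing: H2AC18 averaged 12.61 and 10.30 (adjusted p = 0.116), H2AC19 12.46 and 10.35 (adjusted p = 0.134) and H2AC20 11.85 and 9.71 (adjusted p = 0.101). Their probes cannot be assumed to tell the copies apart. Without LPS sample 1 or control sample 1, limma called 0 histone genes lower, where 23 and 20 had an unadjusted p under 0.05, and 1 without either of the other control arrays. Camera gave an adjusted p of 7.67e-17 for the ribosomal and 0.000685 for the histone family, and adjusted p-values of 0.0805 and 0.225 with an estimated correlation. The ribosomal and histone families were picked on these arrays too, so their counts and p-values are not independent evidence of the direction.

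LPS samples 1 and 2 lay between the control-labelled arrays and LPS sample 3. On the linear scale, and only if the deposited values are plain log2, the share of control-like signal in LPS sample 1 had a median of 0.248 over 357 probes higher in the controls and 0.260 over 311 probes higher in LPS sample 3, and in LPS sample 2 it was 0.438 and 0.445. The medians of the probe sets differed by at most 0.0115, as a mix of 2 kinds of RNA or of cells would give. However, medians of single lists, of 5 to 35 genes each, ran from 0.102 (ribosomal) to 0.308 (prostaglandin) in LPS sample 1 and from 0.290 (contractile) to 0.579 (prostaglandin) in LPS sample 2. The ratio of the observed to the simulated interquartile range of the share was 0.936 and 1.166 for probes higher in the controls, but 1.502 and 2.077 for probes higher in LPS sample 3. A bound set before this result asked a mix to keep all 4 ratios under 1.5, which was not met. The bound set against a mix, every ratio at 1.5 or more, was not met either, so the spread cannot decide. Across probes, LPS sample 2 minus sample 1 followed the control mean minus LPS sample 3 (r = 0.60, no array in common). This argues only against noise unrelated to the difference between the groups. It restates the order of the arrays, so a difference in array quality along the same direction would give the same r and stays open. A mixed sample may account for the order of the 3 arrays, a culture in which a part of the cells responded would look the same, and a response of graded strength in every cell was not tested apart.

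The interferon, cytokine, chemokine and NF-kB lists had lower medians in the LPS-labelled arrays, against the direction in which LPS is known to act. Exchanged group labels may account for this. Of the 4 lists, 3 passed in that direction with camera and none in the other. With an estimated correlation 0 of the 4 passed (adjusted p from 0.312 to 0.394). Of single genes that LPS can induce, CSF3, IL1B, CCL7 and CCL20 were called lower (adjusted p from 0.00513 to 0.0342). CSF3 and CCL20 averaged 7.36 and 7.41 in the LPS-labelled arrays, near the bottom of the scale. Without LPS sample 1, control sample 2 or control sample 3, limma called 0 chemokines lower. IL6, CXCL8 and CXCL10 averaged lower without passing. Against these, VCAM1 rose by 1.76 on 1 of its 3 probes. A response of the control-labelled cells to transfected DNA could also raise interferon genes, and the interferon median lay below the NF-kB median (difference -1.69), most of all in LPS sample 3 (-3.54 and -0.11, against -1.25 and -0.19 in LPS sample 1 and -0.80 and -0.18 in LPS sample 2). The NF-kB median does not describe each member, since 16 of 24 averaged lower and 8 higher. SOD2, on its brightest probe, read 12.6, 13.1 and 10.7 in LPS samples 1, 2 and 3, and TNFAIP3 8.7, 9.1 and 8.1. The difference in medians therefore depends on the members chosen for each list. An LPS response with exchanged labels could give the same values, so these explanations cannot be told apart here, because transfection, LPS and group coincide in the labels. A true effect of LPS in the labelled direction stays open too. Leukocytes as a large part of the control-labelled cultures are argued against by their markers. Only 1 of 13 leukocyte markers, CD68, had a control mean above the upper quartile of all values (7.86), and the next highest, AIF1, averaged 7.64. A small share of leukocytes, or leukocytes of 1 kind, stays open, because values near the bottom of the range are compressed and the list mixes several kinds. A first test asked that PTPRC, TYROBP and CD163 stay under percentile 60 of all probes in each control-labelled array. It had left leukocytes open, with CD163 at 60.3, and was replaced after that.

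The 10 splits of the 6 arrays into 3 and 3 included 1 with as many as 3617 called genes, the labelled one, and the highest of the others had 0 (1448 at an unadjusted p under 0.05, against 6926). With 10 splits the share cannot go under 0.1, so they are too few to decide. A check for mixed-up samples put 0 of the 6 arrays out of place with a set of 8 genes and a cutoff chosen after a first version, with more genes and another cutoff, had put 2 out of place, so it does not exclude a mix-up. A fixed list of genes that vary between people was used to look for a difference in donors between the groups. Of its 28 measured members, limma called 5 higher and 0 lower, against 1759 and 1858 of all 19951 genes. Of 11 members whose mean lay above the upper quartile, 2 differed by at least 1 log2 unit, where 7.52% of all such genes did. These counts are too small to decide, so a difference in donors stays open.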
